A study of Homo sapiens with 39 samples.

How the data were processed

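The series holds RNA sequencing of frozen biopsies of hormone receptor positive, HER2 negative metastatic breast cancer, taken before treatment with palbociclib, which inhibits CDK4 and CDK6, and letrozole, which lowers oestrogen. The labels list 39 libraries, all in 1 group of baseline tumours, with no outcome, biopsy site or subtype. The tables used here hold 28 of them, and the other 11 libraries were not analysed here. The 28 all carry the same digit in their titles and the 11 all carry another. The subset therefore follows a code that the labels do not explain. Each library was taken as a separate tumour and numbered in the order of the labels. Nothing in the labels says which libraries, if any, share a patient, so the p-values measure the spread between these libraries. Those of the amplicon lists come from random lists of genes and do not measure that spread.

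Per the labels' protocols, the authors enriched the RNA libraries for exonic sequence by capture before sequencing, so transcripts outside the capture targets are under-represented and levels of different genes are not on 1 scale. The authors deposited a table of whole-number counts per gene and library, with no normalization, and a table of values named as conditional quantile normalized (CQN), a method that adjusts for GC content and gene length. These deposited CQN values are on a log2 scale as judged from the values: over 7239 genes with at least 200 counts in every library, they rose by 0.892 per unit of log2 CPM (r = 0.945 across genes, which are not independent replicates). The submitters' processing notes name GRCh38 and hg38 as the genome build. The aligner, the counting program, its strand setting, the annotation release and the CQN settings are not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain. Gene symbols, identifiers and coordinates are those of the deposited tables, and 40372 of the 42070 gene identifiers matched the gene name table at hand.

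Total counts ran from 11312618 to 72518459 per library (median 35845993.5), and 15832 to 19914 genes had at least 10 counts. No 2 libraries of the 378 pairs held identical values, and the pairwise r of log2 CPM over 11286 genes with at least 50 counts in every library ran from 0.659 to 0.939. X-inactivation and Y-linked genes (145 genes) were left out of all tests. CPM and log2 CPM were computed from the counts with TMM scaling and a prior count of 2. A gene counted as detected where its CPM was at least 1 in at least 50% of the tumours.

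With 1 group, the comparisons fixed before the data were examined were the levels of 393 genes in 32 lists, 3 axes of variation, 34 relations and 5 lists of genes from regions often amplified in breast cancer. All 393 genes were found, 5 of them under an older symbol. The lists covered the proliferation score, E2F and cell cycle, the CDK4/6 and RB pathway, luminal identity, oestrogen response, basal epithelium, growth factor receptors and PI3K, the 8p11, 11q13, 17q12, 20q13 and 8q24 amplicons, T cells, B cells, plasma cells, macrophages, interferon response, antigen presentation, fibroblasts and matrix, endothelium, hepatocytes, lung epithelium, bone cells, red cell precursors, granulocyte precursors, keratinocytes, adipocytes, skeletal muscle, mesothelium, lymph node stroma, immediate early genes and housekeeping genes. A list score was the mean over its genes of log2 CPM standardized over the tumours, rescaled to an SD of 1 over the tumours.

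Each axis was a continuous term in edgeR's quasi-likelihood test (edgeR 4.0.16 with R 4.3.3, robust fit, filterByExpr, Benjamini-Hochberg adjusted p under 0.05): the score of 11 proliferation genes, log2 CPM of ESR1, and the score of 14 T cell genes, each scaled to an SD of 1. Genes that made up a score stayed out of its test. Effects are log2 changes per SD of the axis with their standard errors. Lists with at least 3 tested members were tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. Relations were tested by Pearson's r and Spearman's rho with 2-sided permutation p from 100000 resamples, adjusted over the 34 relations. A variable was to be treated as clustered where a mixture of 2 normal components (mclust 6.1.1) beat 1 by over 10 in BIC, held at least 6 tumours in each and lay over 2.83 pooled SDs apart. None met all 3 conditions. The mean pairwise r within each amplicon list was set against 10000 random lists matched on mean expression in 20 bins, with a 1-sided p.

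The genes named below were chosen by a rule fixed before the data were examined: up to 4 members of each list past the threshold with the smallest adjusted p, any member of the CDK4/6 and RB pathway list, the 5 genes with the largest change in each direction past the threshold at a mean log2 CPM of at least 2, any listed gene for levels, and the 10 genes of largest spread. Immunoglobulin and T cell receptor segments and genes with no symbol were not named. Names outside the rule are marked as chosen after their values were seen.

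On counts simulated from the real means and library sizes, with 200 genes changed, the edgeR step recovered 56% of genes changed by 0.5 per SD and 92% of those changed by 1 on the proliferation axis (20334 genes tested), 57% and 92% on the ESR1 axis (19999 genes) and 46% and 93% on the T cell axis (20334 genes). Unchanged genes made up 4.52%, 3.87% and 3.47% of the calls. The simulated genes varied independently of one another, unlike those of the tumours, so these shares may not hold for the real counts. A comparison of 22 against 6 libraries recovered 1% and 20%, so it can miss most differences of that size. The relation step recovered 6 of 6 planted relations and called 0 of the others, and the amplicon step recovered its 1 planted list and called 0 others. All were planted as strong relations, so these steps do not show how often weaker relations are missed.

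Alternatives fixed beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no count filter, limma on the CQN values, total count, title letter or list scores (hepatocyte, T cell, fibroblast and keratinocyte) as covariates, and leaving out the 2 tumours farthest from the median. The titles carry a letter and a digit that the labels do not explain. The digit was the same in all 28 libraries, so the comparison by digit, its alternatives, the digit as a covariate and the libraries of the other digit alone were not run. A comparison by the title letter (22 libraries with the most common letter against 6 that pool 2 other letters) took its place. That comparison, leaving out each tumour in turn, leaving out the 6 tumours with ALB at 1000 CPM or more, and the mitochondrial share as a covariate were added after the data were examined. The fits used 28 tumours rather than the 39 planned. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 handled the other steps.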

Results

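RNA from 28 frozen biopsies of hormone receptor positive, HER2 negative metastatic breast cancer, taken before palbociclib and letrozole, was measured as exome-captured read counts per gene. All 28 libraries belonged to 1 group of baseline tumours, so the results describe levels and how genes varied together from tumour to tumour. Total counts ran from 11312618 to 72518459 per library, with a median of 35845993.5. Protein-coding genes held 95.9 to 98.4% of the counts, mitochondrial genes 0.156 to 2.39%, and no gene more than 4.0% of any library. A TMM-scaled CPM of at least 1 in at least 50% of the tumours was found for 311 of the 393 listed genes. Levels are medians in CPM over 28 tumours with the range, and coordinates are on GRCh38.

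Luminal and oestrogen-responsive genes were detected throughout their lists, with wide differences between tumours. The oestrogen receptor gene ESR1 (chromosome 6, 151656691 to 152129619) had a median of 288.5 CPM and ranged from 42.1 to 1887, with an SD of 1.44 on the log2 scale (n = 28). GATA3, a luminal transcription factor, stood at 348.8 CPM (44.9 to 1690), its partner FOXA1 at 162.5 (62.5 to 420.9), and the luminal keratin gene KRT19 at 862.6 (18.5 to 2556). All 19 luminal identity genes and all 24 oestrogen response genes were detected, with list means of 7.89 (SD 0.49 over tumours) and 6.07 (SD 0.69) in log2 CPM. PGR, the progesterone receptor gene and an ESR1 target, varied more, from 1.06 to 345.1 CPM around a median of 44.3 (SD 2.63). ERBB2, the gene of HER2, stayed at or below 542.9 CPM (median 253.7, lowest 52.4).

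The genes of the pathway that palbociclib inhibits were expressed in these tumours with unequal spread. CDK4 (chromosome 12, 57747727 to 57756013) had a median of 46.1 CPM (19.97 to 84.6, SD 0.50 in log2, n = 28), and CDK6 (chromosome 7, 92604921 to 92836594) stood at 8.32 CPM (3.72 to 30.1, SD 0.71). RB1, the tumour suppressor that these kinases phosphorylate, was among the steadier genes at 74.7 CPM (34.2 to 108, SD 0.35). CCND1, which encodes the cyclin D1 partner of CDK4, ranged from 31.1 to 2125 CPM around 158.2 (SD 1.68). CDKN2A, which encodes a CDK4 inhibitor, had a median of 4.89 CPM (0.503 to 17.9), and CCNE1, the cyclin E1 gene, one of 2.79 CPM (1.01 to 63.5). The proliferation marker genes MKI67 and TOP2A spanned 15.7 to 1314 CPM and 7.77 to 506.7 CPM, around medians of 277.8 and 138.1.

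Genes of other cell types and tissues differed widely between tumours, and many of those of other tissues were under 1 CPM in most tumours. Collagen COL1A1 had a median of 4708 CPM (667 to 41760), the macrophage gene CD68 132.4 CPM, the endothelial gene VWF 182.9 CPM and the T cell gene CD3E 5.58 CPM. ALB, the serum albumin gene made by hepatocytes, had a median of 2.80 CPM and a highest value of 23600. It reached 1000 CPM in 6 tumours and stayed under 10 CPM in 17. In the highest tumour for each, listed genes of other tissues reached 16690 CPM for the haemoglobin gene HBB (median 88.6), 4608 for MPO of granulocyte precursors, 1910 for IBSP of bone, 527.8 for ADIPOQ of fat, 522.9 for the skin keratin KRT1 and 467.4 for ACTA1 of skeletal muscle. Among the lung genes, the surfactant genes SFTPB and SFTPA2 did not exceed 4.23 and 13.1 CPM, and AGER reached 29.7 CPM.

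Of the 13172 genes with a mean log2 CPM of at least 2 (median SD 0.58), those with the largest spread joined genes of liver with secretory and luminal genes. Among them, SDs in log2 CPM were 5.35 for ALB, 5.08 for CPB1, 4.96 for APOB, 4.91 for SCGB2A2 (mammaglobin), 4.84 for HP, 4.49 for TFAP2B, 4.40 for KCNJ3, 4.10 for SCGB1D2 and 4.07 for ANKRD30A. SCGB2A2 reached 1000 CPM in 7 tumours and was under 10 CPM in 9, and ANKRD30A, a breast differentiation gene, ranged from 0.132 to 9959 CPM.

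**Figure D1:**
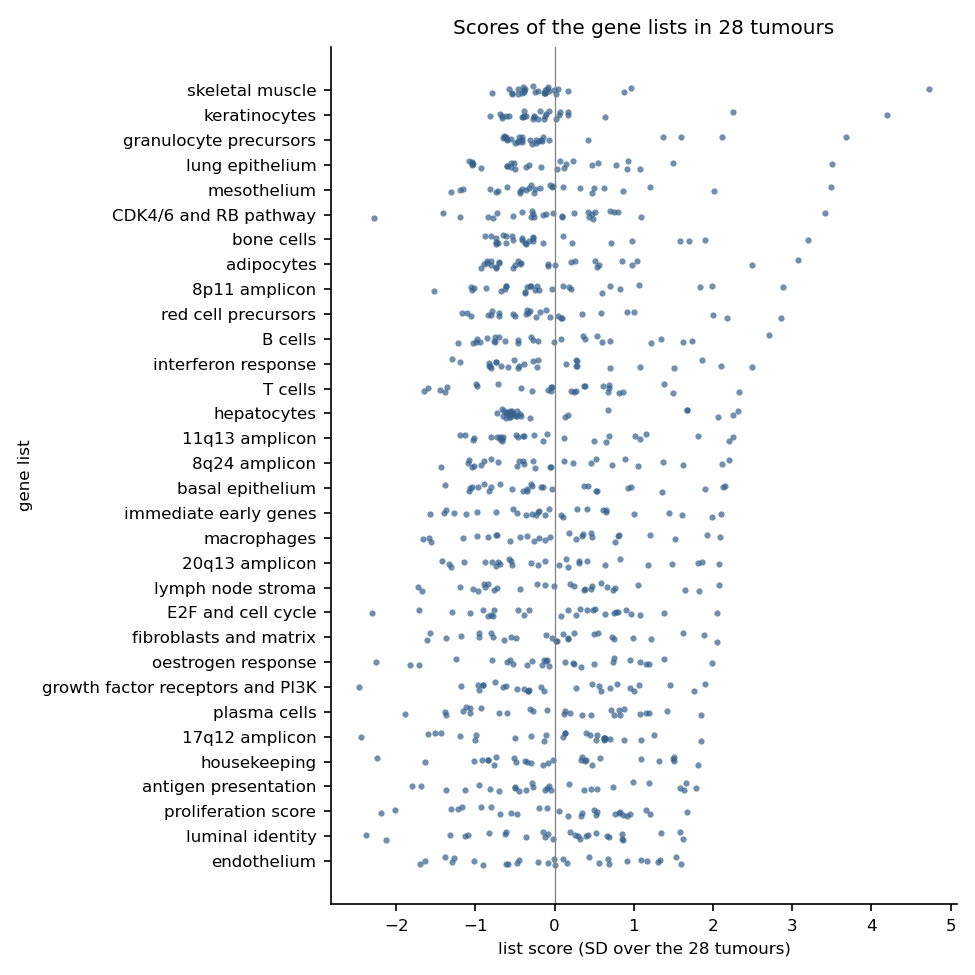
Each point is the score of 1 gene list in 1 of 28 tumours, in SDs of that score over the tumours, with the lists along one axis and the score along the other. Scores of lists such as hepatocytes and skeletal muscle lie close together with a few tumours far above the rest, and 6 tumours held ALB at 1000 CPM or more.

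The first axis asked which genes follow proliferation, the process that CDK4/6 inhibition slows. Cell cycle genes rose together with the 11-gene score. The highest score was that of tumour 34 (1.68), whose most abundant gene was the haemoglobin gene HBB. Whether its score arose in tumour cells was not tested. Leaving out any 1 tumour kept 35 to 37 of the 37 E2F and cell cycle genes past the threshold. The cyclin gene CCNA2 rose by 1.21 ± 0.06 (log2 change per SD of the score ± SE, n = 28; edgeR quasi-likelihood, adjusted p = 1.04e-13), CCNB2 by 1.44 ± 0.09, and the spindle genes TPX2 and BUB1B by 1.26 ± 0.08 and 1.23 ± 0.08. Of the 37 E2F and cell cycle genes, 36 rose and MCM5 did not pass (0.32 ± 0.11, adjusted p = 0.0664), while 37 passed adjusted over the list alone. The list stood apart from other genes with a median of 1.11 (camera, adjusted p = 6.39e-10 with an estimated correlation). The score and the list share no gene, but both hold cell cycle genes. This outcome was therefore largely set by how the axis was made. Over all genes, 1653 of 20323 passed, 1001 higher and 652 lower. Among the amplicon lists, AURKA on 20q13, a mitotic kinase gene that the cell cycle list also holds, rose by 0.90 ± 0.11, and ATAD2 and NDUFB9 on 8q24 rose by 0.61 ± 0.16 and 0.56 ± 0.14. The 20q13 list had 2 of 8 genes higher and 1 lower (5 adjusted over the list alone), of which RBM38 (0.67) did not pass without tumour 34 and BCAS1 (−0.92) without tumour 18. The 8q24 list had 2 of 9 higher (5 adjusted over the list alone; adjusted p = 0.54 with an estimated correlation).

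Most of the CDK4/6 and RB pathway genes did not pass the threshold with the score. RBL1, an RB1 relative and E2F target, rose by 0.39 ± 0.10 (adjusted p = 0.011), and the inhibitor gene CDKN2D by 0.54 ± 0.15 (adjusted p = 0.0228), a call that ended without tumour 34. These were 2 of 20 genes (4 adjusted over the list alone; adjusted p = 0.886 with an estimated correlation). In edgeR 7 of the 20 had an unadjusted p under 0.05, DESeq2 called 4 (3 higher and 1 lower), and limma on the CQN values 1. RB1 (0.14 ± 0.07, adjusted p = 0.212), CDK4 (0.09 ± 0.09) and CDK6 (0.09 ± 0.14) did not pass, and CCND1 (1.01 ± 0.33) had adjusted p = 0.0574 in edgeR and 0.00177 in DESeq2. No luminal gene of 19 and no oestrogen response gene of 24 passed in edgeR, where 7 and 4 had an unadjusted p under 0.05, DESeq2 called 3 and 4, and limma on the CQN values 0 and 0. Leaving out tumour 2, 6, 19 or 20 brought 1 luminal gene past the threshold and tumour 18 or 34 brought 2, and leaving out tumour 2 or 34 brought 1 oestrogen response gene. The housekeeping genes TFRC (0.64 ± 0.14), GAPDH (0.54 ± 0.14) and HPRT1 (0.35 ± 0.10, not past the threshold without tumour 4, 22 or 28) rose, 3 of 10 (4 adjusted over the list alone; adjusted p = 0.179 with an estimated correlation).

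Endothelial genes were lower in tumours with a high score, as were some fibroblast and basal genes. The endothelial receptor genes TIE1 and CLEC14A fell by 0.51 ± 0.08 and 0.61 ± 0.10, and 9 of 10 endothelial genes fell (9 adjusted over the list alone; median −0.51; adjusted p = 0.0217 with an estimated correlation). The collagen gene COL3A1 fell by 0.97 ± 0.16 and DCN, the decorin gene, by 0.96 ± 0.18. Of the fibroblast and matrix genes, 9 of 14 fell (12 adjusted over the list alone; median −0.77; adjusted p = 0.179 with an estimated correlation), while FN1 did not pass (−0.08 ± 0.28). This count was 5 without tumour 7, 17, 23 or 26 and 4 without tumour 24 or 34. The basal keratin genes KRT14 and KRT5 fell by 2.94 ± 0.58 and 2.38 ± 0.51 and TP63 by 1.34 ± 0.30, with 4 of 13 basal genes lower (8 adjusted over the list alone; adjusted p = 0.0633 with an estimated correlation). With hepatocyte, T cell, fibroblast and keratinocyte scores in the model, 2 of the 24 fibroblast and endothelial genes passed (median −0.25 against −0.62), although 14 of the 24 make up the fibroblast score in that model, and the named basal genes, RBL1, ATAD2 and NDUFB9 did not pass.

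Genes of other tissues moved with the score as well. All 20 hepatocyte genes rose (20 adjusted over the list alone), by a median of 4.39, among them ALB (4.48 ± 1.04, adjusted p = 0.00636), APOA2 (6.11 ± 1.32) and TTR (5.59 ± 1.18). The list did not stand apart with an estimated correlation (adjusted p = 0.713). Without the 6 tumours with ALB at 1000 CPM or more, edgeR called 0 of the 20 (median 1.20) and 702 genes in all, where ALB is itself 1 of the 20. With the list scores in the model, which hold these 20 genes, it called 537 genes in all. Limma on the CQN values called 1 of the 20, and edgeR with the title letter in the model 9. Granulocyte precursor genes such as AZU1 (2.42 ± 0.50) rose, 8 of 10 (9 adjusted over the list alone), but 0 without tumour 34. Keratinocyte genes such as KRT10 (−1.63 ± 0.35) fell, 4 of 8 (7 adjusted over the list alone), but 0 without tumour 5, where KRT10 had 0.07 and FLG 1.13. Both lists had adjusted p = 0.886 with an estimated correlation. The genes with the largest changes at a mean log2 CPM of at least 2 were ALB, HP (4.12), APOB (4.09), TF (2.58) and CYP2E1 (2.35), all hepatocyte genes. Those with the largest changes downward were PIGR (−1.93, not past the threshold without tumour 4), SFRP2 (−1.84), KRT10 (not past the threshold and of opposite sign without tumour 5), TNN (−1.44) and MFAP4 (−1.37). The smaller counts were 3 of 10 skeletal muscle genes higher (7 adjusted over the list alone; 0 without tumour 12 or 31 and 1 without tumour 5, 19 or 28) and 1 of 10 adipocyte genes lower (LEP, 0 without tumour 19, 3 without tumour 34). Of the red cell precursor genes 2 of 8 were higher and of the mesothelial genes 1 of 6, and leaving out 1 library changed each count for 12 of the 28, to between 0 and 1 for the red cell genes and to 0 or 2 for the mesothelial genes.

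In 15 lists edgeR called 0 of 165 members on this axis, with 25 at an unadjusted p under 0.05, 14 called by DESeq2 and 2 by limma on the CQN values. The 11q13 list was among them (5 of 6 genes adjusted over the list alone; adjusted p = 0.781 with an estimated correlation), with 4 genes past the threshold without tumour 34, 2 without tumour 24 and 1 without tumour 6, 8 or 22. The 17q12 and B cell lists had medians (−0.05 and −0.01) opposite in sign to their means (0.09 and 0.03), and their tests pointed down and up. With the preset correlation 9 of 31 lists passed, and the cell cycle and endothelium lists were the 2 that held with an estimated correlation. In limma on the CQN values the balance turned, with 405 genes higher and 510 lower.

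The second axis asked which genes follow ESR1, whose product letrozole deprives of oestrogen. CCDC170 (chromosome 6, 151494030 to 151621193), the gene beside ESR1 on its upstream side, rose by 0.79 ± 0.13 per SD of ESR1 (n = 28; edgeR, adjusted p = 0.0113), and it passed in every refit that left out 1 tumour. Skeletal muscle genes such as TNNC2 (1.71 ± 0.27), MYH2 (2.93 ± 0.51), CKM (2.40 ± 0.45) and MYLPF (1.54 ± 0.29) rose, 5 of 10 (8 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation), but 0 without tumour 12. LXN fell by 0.68 ± 0.14 (adjusted p = 0.0468) and passed in 9 of the 28 refits.

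No oestrogen response gene passed alone on the ESR1 axis, although the list's median was positive. Over the 24 genes it was 0.21, edgeR called 0 (2 adjusted over the list alone) with 9 at an unadjusted p under 0.05, and DESeq2 and limma on the CQN values called 0 (camera, adjusted p = 5.09e-06 preset, adjusted p = 0.158 with an estimated correlation). PGR had a change of 0.78 ± 0.37 (adjusted p = 0.467). Among 18 other luminal genes edgeR called 0, with 3 at an unadjusted p under 0.05, and DESeq2 and limma on the CQN values called 0 (adjusted p = 0.43 with an estimated correlation). RB1 (−0.05 ± 0.07) and CCND1 (0.35 ± 0.32) did not pass. In all, 14 of 19998 genes passed, 9 higher and 5 lower, while DESeq2 called 74 higher and 93 lower and edgeR with no count filter 105 and 120. In 31 of the 32 lists edgeR called 0 of 370 members, with 48 at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma on the CQN values. With the preset correlation 13 lists passed and with an estimated one 0. The cell cycle list had a median of 0.00, a mean of −0.03 and a test pointing up, and the bone list a median of 0.23 and a test pointing down.

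The ESR1 count moved with the settings. Without tumour 1 it was 100 (18 higher and 82 lower, with 7 granulocyte and 4 red cell precursor genes lower), without tumour 33 it was 62, and without tumours 36, 19, 24, 20 and 10 in turn it was 37, 30, 29, 23 and 22. It was 9 without tumour 4, 5, 14, 18, 23, 25 or 31, 8 without tumour 8 and 6 without tumour 12. Limma on the CQN values and edgeR with the mitochondrial share in the model called 0 (1205 and 1948 genes at an unadjusted p under 0.05), and CCDC170 had adjusted p = 0.706 and 0.0679 there.

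The third axis asked which genes follow T cell content. B cell and plasma cell genes rose with the T cell score. The B cell surface gene MS4A1 rose by 2.80 ± 0.28 per SD (n = 28; edgeR, adjusted p = 3.06e-08) and BLK by 2.11 ± 0.23. All 10 of 10 B cell genes rose (10 adjusted over the list alone; median 2.08; adjusted p = 0.00322 with an estimated correlation). POU2AF1 rose by 1.61 ± 0.25 and FCRL5 by 1.86 ± 0.31, and 7 of 7 plasma cell genes rose (7 adjusted over the list alone; median 1.47; adjusted p = 0.00504 with an estimated correlation). The antigen presentation genes NLRC5 (0.80 ± 0.14), CIITA (0.61 ± 0.10) and TAP2 (0.48 ± 0.10) rose, 3 of 9 (7 adjusted over the list alone; adjusted p = 0.0208 with an estimated correlation; 6 without tumour 22). CD74 lay just beyond the threshold (0.35 ± 0.10, adjusted p = 0.0501). Lymph node chemokine CCL19 rose by 1.97 ± 0.37, and 3 of 6 lymph node stroma genes rose (5 adjusted over the list alone; adjusted p = 0.0208 with an estimated correlation). Of these, CR2 (1.57 ± 0.32) is also on the B cell list and CCL21 (1.60 ± 0.43) did not pass without tumour 36.

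In all 880 of 20320 genes passed on this axis, 780 higher and 100 lower. The lower genes numbered 485 (827 higher) without tumour 23, 276 in DESeq2 and 319 with no count filter. Of the pathway that palbociclib targets, CCND2, a cyclin gene also used by lymphocytes, rose by 0.64 ± 0.15 (adjusted p = 0.0103). CDKN1A fell by 0.61 ± 0.17 (adjusted p = 0.0324, not past the threshold without tumour 4, 22 or 36). These were 2 of 20 genes (2 adjusted over the list alone; adjusted p = 0.774 with an estimated correlation). The chemokine CXCL10 rose by 1.19 ± 0.31, the 1 of 14 interferon response genes past the threshold (3 adjusted over the list alone; 0 without tumour 23; adjusted p = 0.719 with an estimated correlation). CXCL12 rose by 0.73 ± 0.22 (adjusted p = 0.0498), the 1 of 24 oestrogen response genes past the threshold (0 adjusted over the list alone; 2 without tumour 23; adjusted p = 0.636 with an estimated correlation), and passed in 8 of the 28 refits. Among 8p11 genes ERLIN2 and BAG4 fell by 0.60 ± 0.17 each, 2 of 11 (10 adjusted over the list alone; adjusted p = 0.636 with an estimated correlation). That count was 6 without tumour 23, 0 without tumour 4, 14, 25 or 36 and 1 without tumour 1, 3, 6, 7, 19, 28 or 33.

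Granulocyte precursor genes such as ELANE (5.10 ± 1.18) rose with the T cell score, 7 of 10 (10 adjusted over the list alone), and red cell precursor genes such as AHSP (4.44 ± 1.11), 3 of 8 (6 adjusted over the list alone; 5 without tumour 22). Both counts were 0 without tumour 34, and both lists had adjusted p = 0.719 with an estimated correlation. MSLN fell by 1.496 ± 0.34, the 1 of 6 mesothelial genes past the threshold (2 adjusted over the list alone), a count of 0 without tumour 22 (MSLN at 0.14) and of 2 without tumour 2, 4, 6, 17, 25 or 26. The largest changes at a mean log2 CPM of at least 2 were S100A8 (2.78, in 23 of the 28 refits), SPTB (2.55), PIGR (2.30, not without tumour 4), FCN1 (1.99) and IGLL5 (1.73). Lower with the score were CEL (−1.34) and CSPG4 (−0.97), which did not pass without tumour 2, TUBB2B (−1.28, not without tumour 25), MAPK8IP1 (−1.02, not without tumour 14, 25 or 36) and BMP8A (−0.98, not without tumour 2, 4, 17 or 36). In 20 lists edgeR called 0 of 246 members, with 26 at an unadjusted p under 0.05, 21 called by DESeq2 and 2 by limma on the CQN values. The macrophage list was among them (median 0.16), as was the hepatocyte list, of which 15 genes were lower without tumour 23. With the preset correlation 11 of 31 lists passed and with an estimated one 4. The cell cycle list (median 0.01, mean 0.04) had a test pointing down, and the basal list a median of −0.02 and a mean of 0.44.

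**Figure D2:**
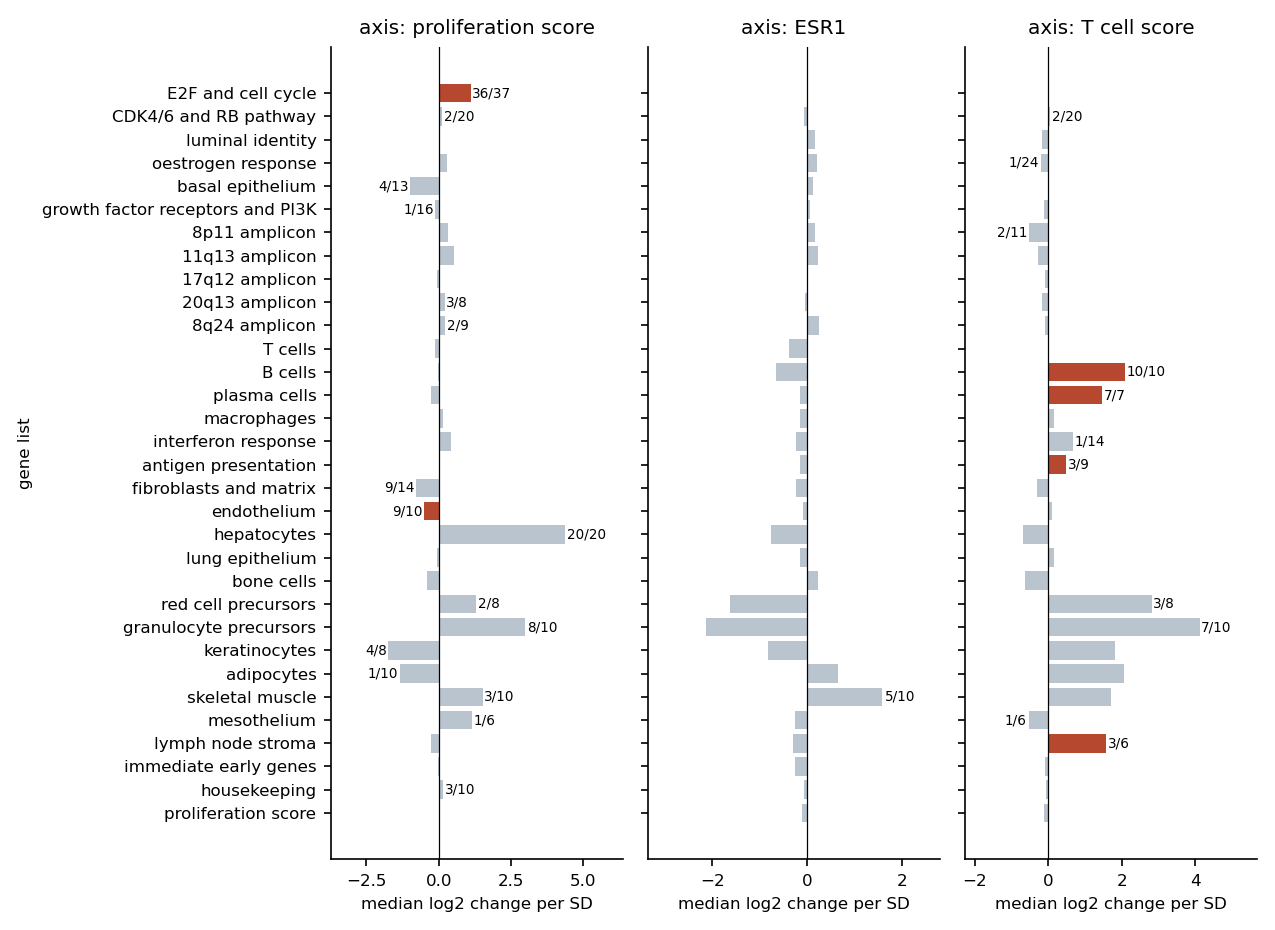
Bars give the median log2 change per SD of the proliferation score, ESR1 or the T cell score over the tested genes of each list (28 tumours), red where camera had an adjusted p under 0.05 with an estimated correlation, with the genes past the threshold and the genes tested beside each bar. The red lists are E2F and cell cycle (1.11) and endothelium (−0.51) on the first axis, none on the second, and B cells (2.08), plasma cells (1.47), antigen presentation (0.48) and lymph node stroma (1.58) on the third.

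Direct relations between 34 pairs of genes or scores asked which CDK4/6 pathway genes track proliferation and which partners vary together. FOXM1, a mitotic transcription factor gene, followed the proliferation score at Pearson r = 0.932 (n = 28; permutation p = 1e-05, the smallest that 100000 resamples can give; BH adjusted p = 6.8e-05; Spearman rho = 0.863, p = 1e-05, adjusted p = 0.000113). TK1 and E2F1 did so at r = 0.824 and 0.821 (both p = 1e-05, adjusted p = 6.8e-05; rho = 0.782 and 0.783, p = 1e-05 and 2e-05, adjusted p = 0.000113 and 0.000136). Without the 2 farthest tumours r was 0.892, 0.768 and 0.784 for these genes. Within the most common title letter (n = 22) it was 0.908, 0.792 and 0.756. FOXM1, TK1 and E2F1 are on the cell cycle list, so these relations too were largely set by what the score holds. Of the cyclin E genes, CCNE1 had r = 0.655 (permutation p = 6e-05, adjusted p = 0.000291; rho = 0.702, p = 5e-05, adjusted p = 0.000243; r = 0.682 without the 2 farthest and 0.615 within the most common letter). CCNE2 had r = 0.579 (permutation p = 0.00118, adjusted p = 0.00401; rho = 0.536, p = 0.00354, adjusted p = 0.012; r = 0.535 and 0.517), and r = 0.396 with the list scores removed (adjusted p = 0.0969). The fibroblast score went the other way at r = −0.608 (permutation p = 0.0006, adjusted p = 0.00255; rho = −0.698, p = 4e-05, adjusted p = 0.000227; r = −0.604 without the 2 farthest and −0.575 within the most common letter).

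RB1 itself did not reach the threshold with proliferation by Pearson's r. It had r = 0.367 (permutation p = 0.055, adjusted p = 0.134) and 0.302 within the most common letter. By rank RB1 had rho = 0.496 (p = 0.00802, adjusted p = 0.0227). Without the 2 tumours farthest from the median of RB1, r was 0.536 (adjusted p = 0.0141). They include tumour 25, which had the lowest RB1 (5.1 in log2 CPM). On the CQN values r was 0.18, and with the list scores removed it was 0.312 (adjusted p = 0.212). CCND1 (r = 0.357, permutation p = 0.0628, adjusted p = 0.142; rho = 0.31, p = 0.11, adjusted p = 0.22; r = 0.313 without the 2 farthest and 0.23 within the most common letter) did not pass. Neither did CDK4 (r = 0.149, permutation p = 0.448, adjusted p = 0.569; rho = 0.209, p = 0.284, adjusted p = 0.398; r = 0.163 and 0.15). CDK6 did not pass either (r = −0.054, permutation p = 0.787, adjusted p = 0.837; rho = −0.215, p = 0.271, adjusted p = 0.398; r = −0.37 and 0.06). The hepatocyte score had r = 0.407 with proliferation (permutation p = 0.0305, adjusted p = 0.0799; rho = 0.498, p = 0.00779, adjusted p = 0.0227; r = 0.331 without the 2 farthest and 0.405 within the most common letter). Its values fell short of the rule for separate clusters by little, with 8 tumours in the smaller component and a separation of 2.79 against 2.83 pooled SDs.

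ESR1 followed the oestrogen response score at r = 0.525 (permutation p = 0.00409, adjusted p = 0.0126), with rho = 0.42 (p = 0.0269, adjusted p = 0.0704). The relation rested in part on the 2 farthest tumours, without which r was 0.425 (adjusted p = 0.068), and was 0.531 within the most common letter. ESR1 with PGR did not pass (r = 0.414, permutation p = 0.0289, adjusted p = 0.0799; rho = 0.384, p = 0.0434, adjusted p = 0.0984; r = 0.256 without the 2 farthest and 0.376 within the most common letter). ESR1 with FOXA1 had r = 0.347 (permutation p = 0.0706, adjusted p = 0.15; rho = 0.414, p = 0.0294, adjusted p = 0.0714; 0.369 within the most common letter) and 0.532 without the 2 farthest (adjusted p = 0.0141). Neighbours in regions often amplified in breast cancer varied together. ERBB2 with GRB7 had r = 0.857 (permutation p = 1e-05, adjusted p = 6.8e-05; rho = 0.791, p = 1e-05, adjusted p = 0.000113; r = 0.734 and 0.866). CCND1 with PPFIA1 had r = 0.83 (permutation p = 1e-05, adjusted p = 6.8e-05; rho = 0.742, p = 2e-05, adjusted p = 0.000136; r = 0.78 and 0.833). FGFR1 with NSD3 had r = 0.696 (permutation p = 3e-05, adjusted p = 0.00017; rho = 0.568, p = 0.00187, adjusted p = 0.00706; r = 0.572 and 0.752). The fibroblast score followed the endothelium score at r = 0.586 (permutation p = 0.0011, adjusted p = 0.00401; rho = 0.62, p = 0.00052, adjusted p = 0.00221; r = 0.597 and 0.527). In all, 11 of the 34 relations passed by Pearson's r, and the r of those that did not ran from −0.341 to 0.414.

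**Figure D3:**
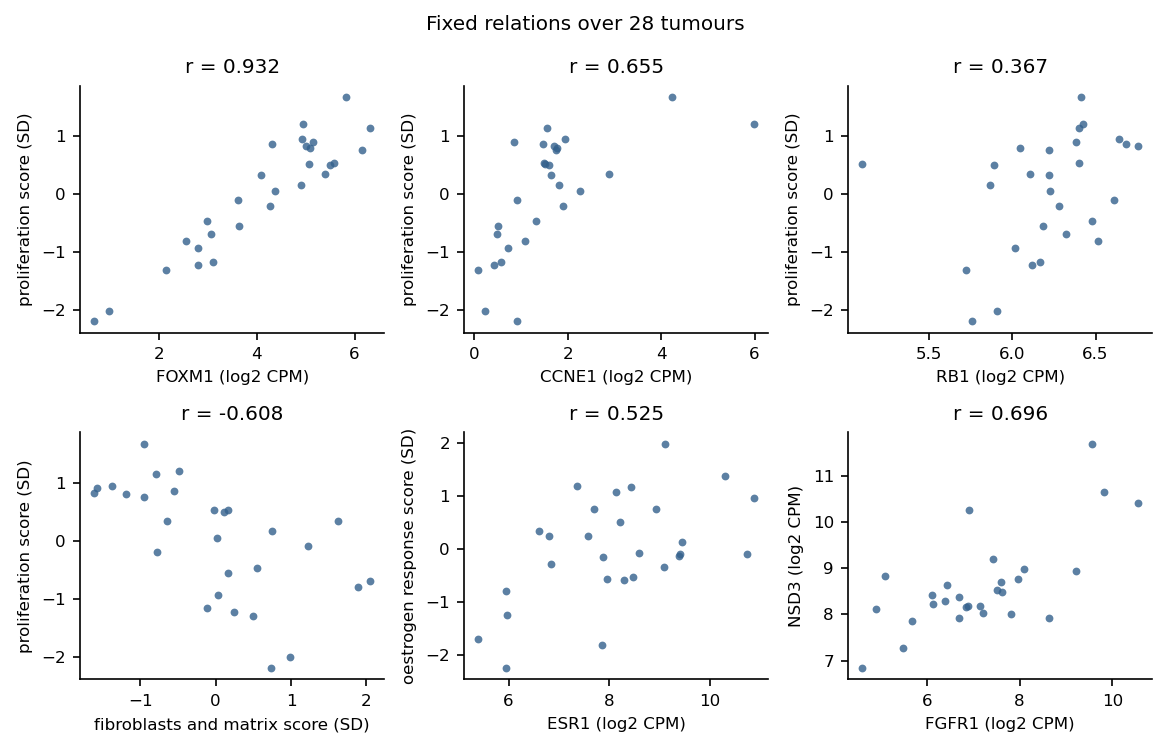
Each point is 1 of 28 tumours, with log2 CPM or list score in SD units on both axes, for FOXM1, CCNE1, RB1 and the fibroblast score against the proliferation score, ESR1 against the oestrogen response score, and FGFR1 against NSD3. FOXM1 lies closest to a line (r = 0.932), RB1 is widely scattered (r = 0.367), and the fibroblast score declines along the proliferation score (r = −0.608).

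Genes from regions often amplified in breast cancer varied together more than random genes of like expression. The random genes were drawn from the whole genome, while the listed genes are neighbours. Of 2200 windows of 10 neighbouring genes, 87.6% also lay above the 95th percentile of shuffled gene orders (median r 0.178). The p-values below therefore do not set these regions apart from other neighbouring genes. The 11 genes of 8p11, from ZNF703 (chromosome 8, 37695751 to 37700021) to the receptor gene FGFR1 (38411138 to 38468834), had a mean pairwise r of 0.791 across 28 tumours. The 95th percentile of 10000 random lists was 0.071. The 1-sided p from these lists was 0.0001, the smallest they can give (BH adjusted p = 0.00017 over 5 lists). It rests on drawing genes rather than tumours, as do the p-values of the other amplicon lists. The 6 genes of 11q13 expressed enough to test, among them CCND1 (chromosome 11, 69641087 to 69654474), had 0.715 against 0.129 (adjusted p = 0.00017). The 9 genes of 8q24 had 0.411 against 0.084 (adjusted p = 0.00017), although MYC, the oncogene of that region, averaged −0.019 with the others. The 5 genes of 17q12 around ERBB2 (chromosome 17, 39687914 to 39730426) had 0.376 against 0.157 (adjusted p = 0.00062), and the 8 genes of 20q13 had 0.05 against 0.088 (p = 0.145). FGFR1 reached 1510 CPM and CCND1 2125 CPM in single tumours.

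The title letter, which the labels do not explain, was tested as a possible batch, with 22 libraries of the most common letter against 6 that pool 2 other letters. BCAN, KRT10 and MAEL, chosen after their values were seen, were lower in the 22 by 5.99 ± 0.98, 3.86 ± 0.64 and 4.16 ± 0.76 in log2 (edgeR, adjusted p = 0.0168, 0.0168 and 0.0469). Tumour 5, on which the KRT10 call on the proliferation axis rested, is among the 6, and whether it carries this difference was not tested. BCAN, KRT10 and MAEL were the 3 of 19999 genes past the threshold, and 1170 had an unadjusted p under 0.05. DESeq2 called 28 (19 higher and 9 lower in the 22). EdgeR with total count in the model and limma on the CQN values called 0 (1033 and 663 at an unadjusted p under 0.05). The 20 hepatocyte genes had a median log2 difference of 7.05, higher in the 22, with 0 past the threshold. The 7 keratinocyte genes tested had −4.40, with 1 past it. The letter and the content of these tissues were not told apart.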

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

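The refits without single tumours, without the 6 tumours with ALB at 1000 CPM or more and with the mitochondrial share and the title letter comparison were chosen after the data were examined. Settings chosen beforehand that needed the title digit were not run, since all 28 libraries had the same digit. No paired analysis was possible because nothing in the labels pairs the libraries. The DESeq2 Wald test called 2507 genes on the proliferation axis (1653 in edgeR), 167 on the ESR1 axis (14), 1347 on the T cell axis (880) and 28 by title letter (3). Limma on the CQN values called 915, 0 on the ESR1 axis and 0 by title letter. The list scores as covariates remove what genes share with the hepatocyte, T cell, fibroblast and keratinocyte scores. They gave 537 genes on the proliferation axis (369 of them among the 1653) and 1 on the ESR1 axis. With proliferation they turned the sign of APOC3 (−0.087), FLG2 (1.53) and FLG (1.18). APOC3 is part of the hepatocyte score and FLG2 and FLG are part of the keratinocyte score, so those covariates hold each gene's own values. Without the ALB tumours, a fit with fewer samples, the counts were 702 and 3. On the ESR1 axis they were 225 with no count filter, 4 with the title letter, 106 without the 2 farthest tumours and 0 with the mitochondrial share. By title letter they were 128 with no count filter and 0 with total count. MSLN on the T cell axis turned to 0.20 without the 2 farthest tumours. Leaving out single tumours gave 1297 to 1752 genes for proliferation, 6 to 100 for ESR1 and 669 to 1312 for T cells. Of the list tests, 33 passed with the preset correlation and 6 with an estimated one, which allows for genes of a list varying together. Where no reason is given here, the cause was not tested. Over the alternatives, 1300 values of named genes stayed on their side of the threshold, 242 fell short of it, 4 came past it and 4 turned in direction. Direction was compared only for the 55, 6 and 38 genes past the threshold on the proliferation, ESR1 and T cell axes. The 1300 also hold CDK4/6 and RB pathway genes that were not past it in the main fit and stayed so. Of the 242, 66 came from the list scores as covariates, 62 from limma on the CQN values, 36 from leaving out the ALB tumours and 25 from the title letter as a covariate. The number of relations past the threshold stayed between 10 and 12, and 4 of the 5 amplicon lists passed under each of their 4 alternatives. Totals differed from 11312618 to 72518459, and with total count in the model 1639, 15 and 935 genes passed on the proliferation, ESR1 and T cell axes.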

Other observations

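The windows of neighbouring genes, the genes beside ESR1, the single tumours below, the title letter splits, the refit without the ALB tumours and the test of depth as a cause were chosen after results were seen. Genes beside ESR1 on chromosome 6 had positive changes with it, in order of distance CCDC170 (0.79 ± 0.13 per SD, adjusted p = 0.0113), C6orf211 (151452258 to 151470101; 1.10 ± 0.28, adjusted p = 0.114) and RMND1 (151404763 to 151452181; 0.91 ± 0.28, adjusted p = 0.214), of which CCDC170 alone passed in edgeR. AKAP12, farther out (151239999 to 151358557), had 0.04 ± 0.20 (adjusted p = 0.968).

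Several genes of cell cycle control and growth signalling stood far out in 1 or a few tumours. CCNE1 reached 63.5 CPM against a median of 2.79, and a mixture of 2 components put 2 tumours in its upper part (BIC gain 10.4). The second highest was tumour 34 (4.23 in log2 CPM), whose most abundant gene was HBB. CDKN1B, which encodes the p27 inhibitor, fell to 11.6 CPM in tumour 24 against a median of 72.5 (BIC gain 13.6). In that library ALB was the most abundant gene and the mitochondrial share was the highest of all (2.39%). Whether such values arose in tumour cells was not tested. CCND3 reached 104.6 CPM (median 13.7) and IGF1R 6120 CPM (median 279.2). FGF3, FGF4 and FGF19, growth factor genes on 11q13, had medians of 0 CPM and reached 42.0, 58.5 and 19.5 CPM, with at least 1 CPM in 2, 1 and 2 tumours.

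The number of genes that followed an axis was set against other axes of the same tumours. When the tumours' scores were permuted, 0 of 30 draws called as many genes as the proliferation score (1653; highest draw 104), 0 of 30 as many as the T cell score (880; highest 216) and 1 of 30 as many as ESR1 (14; highest 22). These argue against a random order of the tumours for the first 2 axes, and 30 draws are too few to place ESR1 firmly. Random gene lists of the same size and expression used as axes called as many in 3 of 30 draws for proliferation (median 237, highest 2495) and 9 of 30 for T cells (median 231.5, highest 2004), and random genes matched to ESR1, 26 distinct genes, in 29 of 30 (median 583, highest 3173). Large counts could therefore come from a structure shared by many genes in these tumours, and no count was high enough to set an axis apart. The ESR1 count lay near the low end of its random genes (lowest 13). No biological explanation was tested. For the title letter, 84 of 100 splits of the libraries into 22 and 6, the real one included, gave as many genes (3; highest other split 596), so chance could not be excluded. Splits that call many times more genes point to a structure of the samples, whose cause was not tested.

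On the proliferation axis 20 of 20 hepatocyte genes were higher and 18 of 24 fibroblast and endothelial genes lower, with adjusted p = 0.713 for hepatocytes, 0.179 for fibroblasts and 0.0217 for endothelium with an estimated correlation (camera). Liver tissue in some biopsies is a candidate source of the hepatocyte genes, and it stays open. Without the 6 tumours with ALB at 1000 CPM or more, 0 of the 20 genes passed. Their median went from 4.39 (quartiles 3.13 and 5.49) to 1.20 (0.77 and 1.74). But ALB is 1 of the 20, so the tumours were left out by a gene of the tested list, and the loss of calls cannot tell the source. For the 24 fibroblast and endothelial genes the median change without those tumours was 0.87 times that over all tumours (95% interval 0.738 to 0.984). The interval came from resampling the genes, which vary together, so it does not measure the spread between tumours. Of the 24 genes 11 passed rather than 18, and of the 14 fibroblast genes 3 rather than 9. Whether liver tissue dilutes stroma in part stays open. Depth of the libraries as the whole cause is argued against, since with total count in the model 18 of the 24 still passed. The ratio was 1.001 there (0.996 to 1.143, again from resampling the genes alone). These explanations are technical, and no biological explanation was tested, since the labels give no group for one.

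Genes that lie side by side varied together along much of the genome. In 2200 windows of 10 neighbouring genes, 1 gene kept of each family, the median of the mean pairwise r was 0.178, and 87.6% of windows lay above the 95th percentile of shuffled gene orders (0.075), which argues against gene families that share reads as the whole cause. On the CQN values 85.2% did, with a median of 0.16, which argues against GC content or gene length bias as the whole cause. The CQN settings are not known, so bias that remains in those values stays open. Above every shuffled value lay 196 windows, and 445 on the CQN values. Among those of highest r were CLTC to PPM1D (chromosome 17, 59619689 to 60666280; r = 0.809) and BRF2 to FGFR1 (chromosome 8, 37843268 to 38468834; r = 0.79). Copy number, transcripts that read through into the next gene and shared chromatin stay open, and the labels give no group that tests them.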
